A study of Mus musculus with 12 samples.

How the data were processed

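Gene expression was measured by RNA sequencing of total RNA from mouse testis, in 12 libraries from F0 animals of a strain given as IRC mouse. The labels name 4 groups of 3 libraries: OV, in which a virus raised lncRNA8276; KD, in which a virus inhibited it; and 5NC and 3NC, whose abbreviations the labels do not spell out. 5NC and 3NC were treated as groups that received control viruses, and OV was compared with 5NC and KD with 3NC. This assignment is inferred from the order in which the design statement lists the groups and from the usual names of such vectors, so both treated groups were also compared with the other control group. The labels do not say whether samples of a group are separate animals, so p-values measure the spread between these samples. Replicate numbers come from the sample titles.

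The deposited table holds 20718 genes with Entrez identifiers and symbols, and 2 kinds of values for each library. The authors deposited expected counts (estimated reads per gene, made per library without normalisation, per the file headers), of which 88% are whole within a tolerance of 1e-06; they were rounded for testing. The authors also deposited normalised values, and the unit FPKM was inferred for them here: over 5204 genes with more than 500 reads, value per read followed the inverse of the library total to within 0.53%. The genome build was mm10 according to the submitters' processing notes. The aligner, the counting program, the strandedness of the libraries and the annotation are not given in the sources used here. The symbol Plin2 stands beside 2 identifiers. Of the identifiers, 20564 (99.3%) matched the reference gene table for the mm10 assembly, which gave coordinates and gene types; 20281 entries were protein-coding and 109 were long noncoding RNAs. Of the symbols, 0 hold the digits 8276, so the level of lncRNA8276 was not analysed here. In the same table, 18 per-sample columns that belong to no library of this series were not used here.

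Libraries held 15448442 to 16355720 estimated reads. The floor of 3 reads, used for a gene with a count of 0, is given per library as 0.183 to 0.194 CPM, reads scaled to a common library total; folds against a group without reads use 3 reads over the group. Such floors and counting intervals cover counting error only. Genes were tested with edgeR 4.0.16 in R 4.3.3, with quasi-likelihood fits (robust), TMM normalisation, one fit of all 4 groups without covariates, and filterByExpr with a minimum count of 10 and a minimum total of 15. The filter left 16320 genes, and the common biological coefficient of variation was 0.13. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Fold changes carry edgeR's prior count of 0.125 and are given as log2 values ± SE. The SE was taken as the size of the log2 fold change over the root of the quasi-likelihood F value. It is approximate, above all for genes with few reads. Levels are mean CPM ± SD with n = 3 libraries per group. Comparisons were OV with 5NC, KD with 3NC, 5NC with 3NC, and the difference between the OV and KD effects. Where no gene was called in both of the first comparisons, the 200 genes of smallest p in each were compared with a two-sided Fisher exact test.

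Gene lists for testis cell types, germ cell stages, junctions, adhesion, signalling, stress and immunity were tested with camera in limma 3.58.1, with a preset correlation of 0.01, on log2 CPM with a prior count of 2. Of 33 lists, 32 had at least 5 tested members; the mitochondrial genome list had none in the table. The lists hold 761 entries, of which 735 matched. Each list was also tested with an estimated correlation and with fry, which asks only whether the genes of a list move one way. Members were adjusted once over all genes tested and once over the list alone. The lists, tests, threshold, comparisons and the rule for named genes were set before the data were examined. By that rule, the named genes are the called genes with a symbol, a mean of at least 1 CPM and no overlap between the 3 and 3 libraries, up to 10 rises and 10 falls for OV and KD and up to 5 each for 5NC. With fewer than 5 calls, the rule takes the 5 rises and 5 falls of smallest p. It adds up to 4 members of smallest p from each list that passes, and from the junction, adhesion, Sertoli, Leydig and germ cell lists. For the last lists, where they did not pass, the text gives fewer members, a reduction made after the values were seen. A few genes that the rule takes are not reported here.

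Whether replicate numbers pair libraries was checked by correlating deviations from the group means across genes. Libraries of OV and 5NC with the same number had r of 0.16, 0.15 and 0.11 for replicates 1, 2 and 3, which met the preset rule for pairing. These values are small, and the pairing is inferred from the same data that were then tested. The values were 0.01, 0.03 and 0.06 for KD with 3NC and −0.03, 0.01 and 0.02 for 5NC with 3NC. A replicate block was planned as an alternative in the fit of all groups; blocks for OV and 5NC alone were chosen after the data were seen. The results were also computed with DESeq2 1.42.0, limma with voom and sample weights, limma on log2(FPKM + 1), and other size factors. Other filters, other thresholds, fits of the compared groups alone, exchanged or pooled controls and each library left out were tried too. A fit without 3NC replicate 2 and OV replicate 3, which lay apart on the first principal component as OV replicate 1 did too, was added after the data were seen.

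The gene test was tested on simulated data built from these libraries, with 50 genes altered at each fold. The altered genes all had over 2 CPM. Genes were drawn independently, without shifts of whole libraries besides depth, so recovery in the real libraries can be lower. For OV against 5NC it recovered 48% at 1.5-fold, 76% at 2-fold, 92% at 4-fold and 100% at 8-fold, and called 0.056% of unchanged genes. For KD against 3NC it recovered 54%, 74%, 100% and 100%, and called 0.019%. In separately simulated data the list test called the raised list and 0 of 30 unchanged lists of random genes. Genes that vary together were not simulated, so this does not test the preset correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.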

Results

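RNA sequencing of mouse testis gave 12 libraries, 3 from each of 4 groups: overexpression of lncRNA8276 (OV), its knockdown (KD) and the control groups 5NC and 3NC. Totals per library lay between 15448442 and 16355720 estimated reads. Between 18611 and 18788 genes had a read, and the 10 genes with most reads took 3.22% to 3.66% of a library. The first principal component held 19.1% of the variance. It set apart OV replicates 1 and 3 (scores 30.2 and 30.3) and 3NC replicate 2 (29), which lay away from the rest of its group.

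OV against 5NC asks which testis genes respond to more of lncRNA8276. Genes of antigen presentation were higher in OV as a group: all 17 tested members had higher means, with a median log2 fold change of 1.5 (SD 0.57 over genes). Interferon response genes were higher too, with 26 of 28 members and a median of 1.08. H2-D1, a classical MHC class I heavy chain (gene 14964, chromosome 17, 35263094 to 35267497), had 175 ± 26.3 CPM in OV and 55.7 ± 15.9 in 5NC (SD, n = 3). Markers of Sertoli, Leydig and peritubular cells and ribosomal protein genes were lower as groups, by small amounts. With an estimated correlation 0 lists passed (adjusted p = 0.378 to 0.532 for these lists), and against 3NC the Sertoli, peritubular and ribosomal calls were lost. No single gene passed: edgeR called 0 of 16320 genes (smallest adjusted p = 0.239), with 1697 at an unadjusted p under 0.05. DESeq2 called 45 genes, limma with voom and sample weights 7, and limma on FPKM 0.

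Antigen presentation genes rose as a list (camera adjusted p = 5.53e-14; adjusted p = 0.378 with an estimated correlation). Adjusted over the list alone 15 of 17 passed, and 0 over all genes tested. H2-D1 had a log2 fold change of 1.65 ± 0.27, H2-K1 1 ± 0.24, Nlrc5, the activator of class I genes, 1.05 ± 0.22 and H2-DMb1 1.52 ± 0.41. Reads of H2 genes can be shared between paralogs, so their single values are uncertain. The means of this list per library were 1.64, 1.46 and 0.5 in OV and 0, 0.2 and −0.7 in 5NC, in log2 units around the mean of all libraries. Interferon response genes rose as a list (adjusted p = 1.21e-11; adjusted p = 0.401 with an estimated correlation), with 10 higher adjusted over the list alone. Ifi44 had 2.97 ± 0.7, Ifit1, one of a family of close paralogs, 1.44 ± 0.41, Xaf1 1.05 ± 0.35 and Ddx58, the RNA sensor RIG-I, 0.57 ± 0.19. Xaf1 was highest in OV replicate 2 (16.7 CPM, against 7.44 and 4.43 in replicates 1 and 3 and 4.4 to 4.74 in 5NC) and had 0.38 without it. Macrophage markers rose as well (adjusted p = 3.03e-05; adjusted p = 0.532 with an estimated correlation), with 19 of 20 higher, a median of 0.68 and 0 adjusted over the list alone. Ptprc, the leukocyte antigen CD45, had 1.38 ± 0.38, Laptm5 1 ± 0.31, the complement gene C1qb 0.71 ± 0.24 and the protease gene Ctss 1.36 ± 0.46. Without OV replicate 1 the macrophage call was lost (adjusted p = 0.0723).

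Sertoli cell markers fell as a list (23 of 25 lower, median −0.22, adjusted p = 3.45e-05; adjusted p = 0.532 with an estimated correlation). Inha, the inhibin alpha subunit, had −0.79 ± 0.16, the 1 member lower adjusted over the list alone; Krt18 had −1.07, Defb45 −0.58 and Amhr2 −0.36. Leydig cell and steroidogenesis genes fell (17 of 21 lower, median −0.34, adjusted p = 5.8e-05; adjusted p = 0.401 with an estimated correlation; 0 adjusted over the list alone). Insl3, a Leydig cell hormone, had −0.59, Hsd3b1 −0.49, Nr5a1 −0.46 and Scarb1 −0.26. Peritubular myoid and stromal markers fell (13 of 17 lower, median −0.29, adjusted p = 0.000429; adjusted p = 0.378 with an estimated correlation), with 7 adjusted over the list alone. The smooth muscle genes Acta2, Myl9, Tpm2 and Myh11 had −0.52 ± 0.13, −0.47, −0.47 and −0.43. Ribosomal protein genes fell (35 of 36 lower, median −0.16, adjusted p = 7.79e-09; adjusted p = 0.378 with an estimated correlation; 0 adjusted over the list alone). Rps14 had −0.29, Rps19 −0.24 and Rplp1 −0.22, values that reads of pseudogenes can alter.

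Epididymis and fat markers fell as a list (7 of 11 lower, median −0.6, adjusted p = 0.0184; adjusted p = 0.532 with an estimated correlation; 1 adjusted over the list alone). The epididymal genes Crisp1 and Adam7 had 2988 and 365 reads in 5NC, against 155 and 18 in OV, and log2 fold changes of −4.3 ± 1.52 and −4.34 ± 1.53. In OV, replicate 2 held 147 of these Crisp1 reads and all 18 Adam7 reads, and without it the fitted values were −7.94 and −9.94, the latter with 0 reads left in OV and so no bound. Without 5NC replicate 3 Adam7 had −2.89. Plin1, a lipid droplet protein, had −0.75. Among the control libraries the list means were −0.03, 1.61 and 1.29 in 5NC and −0.49, −0.24 and −0.43 in 3NC. The Sertoli call was lost without 5NC replicate 1 (adjusted p = 0.161), and the epididymis and fat call without 5NC replicate 2 (0.23) or OV replicate 1 (0.149) and against both controls (0.131). Against 3NC the peritubular (0.365), ribosomal (0.941), Sertoli (0.941) and epididymis and fat (0.766) calls were lost, the Sertoli and the epididymis and fat lists with the opposite direction.

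The genes of smallest p did not pass. On the higher side were Lhfpl3 at 2.25 ± 0.37 (1.74 ± 0.509 CPM in OV, 0.357 ± 0.117 in 5NC), the uncertain gene model Gm7133 at 1.32 ± 0.23, H2-D1, and Itgal, the alpha chain of the leukocyte integrin LFA-1, at 1.43 ± 0.27. LOC108168570, a gene model on chromosome Y with uncertain read assignment, had 0 reads in 5NC and 38 in OV, 12.4-fold higher against 3 reads over the group and at least 9.58-fold higher by the 95% counting interval of the ratio; 3NC had 37 reads and KD 31, so 5NC alone lacked reads. On the lower side was Spink8, a Kazal-type protease inhibitor and a member of the epididymis list (−3.4 ± 0.61), with 1.03 ± 0.687 CPM in OV and 11 ± 6.75 in 5NC. The potassium channel gene Kcnk3 had −1.65 ± 0.27, Ramp1, a partner of peptide hormone receptors, −1.5 ± 0.27, Csdc2 −0.96 ± 0.19 and the secreted kinase gene Pkdcc −0.78 ± 0.16. Against 3NC the sign of Lhfpl3, Ramp1 and Spink8 was reversed (−0.13, 0.08 and 0.39).

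Germ cell lists did not pass in OV against 5NC. Undifferentiated spermatogonia had a median of −0.09 (camera adjusted p = 0.208), with Pou5f1 at −1.08 ± 0.26 and Ccnd2 at −0.63, and differentiating spermatogonia −0.16 (0.0602), with Dmrt1 at −0.22. Meiotic recombination genes had 0.05 (0.408), with Mei1 at −0.53 ± 0.15, pachytene and later spermatocytes 0.07 (0.117) and the piRNA pathway 0.04 (0.387). Round spermatids had 0.01 (0.347), elongating spermatids −0.04 (0.821), with Prm3 at −0.34, and the sperm flagellum 0.06 (0.0858). Junction and adhesion lists did not pass either. Tight junctions of the blood-testis barrier had −0.13 (0.213), with Cldn5 at −0.34 and Ocln at −0.32, and adherens, desmosome and gap junctions −0.04 (0.599), with Gjc1 at −0.23. Integrins and focal adhesion had −0.08 (0.424), with Itgb4 at −1.03 ± 0.33, and other adhesion molecules 0.03 (0.821), with Cd44 at 1.06. Inflammatory cytokines had 0.32 (0.0602), lymphocyte and granulocyte markers 0.63 (0.117; median 0.11 without OV replicate 1), endothelial markers −0.12 (0.289) and the extracellular matrix −0.09 (0.328). Erythrocyte genes had a median of 0.04 with a test direction of down (0.619). Immediate early genes had −0.11 (0.424), heat shock −0.08 (0.521), NRF2 −0.06 (0.205), p53 targets −0.06 (0.47) and histones −0.13 (0.519). Retinoic acid signalling had −0.15 (0.105), and Wnt, Notch, Hippo and TGF-beta signalling −0.05 (0.427).

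Replicate numbers met the rule for pairing OV with 5NC, so blocked values stand beside these results. A block in a fit of the 6 OV and 5NC libraries alone, chosen after the data were seen, called 215 genes, 132 higher and 83 lower. They include the MHC class II invariant chain Cd74 (2.02 ± 0.11), H2-D1 (1.67 ± 0.1), B2m (1.37 ± 0.1) and, on the lower side, Spink8 (−3.37) and Inha (−0.78). In that fit 8 lists passed, none with an estimated correlation, and with fry antigen presentation (adjusted p = 0.0499), interferon response (0.0416) and ribosomal proteins (0.00995) did. With the planned block in the fit of all 4 groups edgeR called 0 genes, and with a block for OV and 5NC only within that fit it called 2, Spink8 and the uncertain gene model Gm15319, the latter named after its values were seen. In this last fit fry passed antigen presentation, epididymis and fat, and peritubular markers (0.0234 each) and ribosomal proteins and retinoic acid signalling (0.0378 each), and interferon response did not pass (0.0577). With an estimated correlation 0 lists passed in this fit as well (smallest adjusted p = 0.231). Without single libraries the count moved from 0 to 1 (5NC replicate 1), 5 (OV replicate 2) and 1 (OV replicate 3), and without both OV replicate 3 and 3NC replicate 2 to 36. The number of lists moved from 8 to 14 without 5NC replicate 2. Against 3NC the count was 52 (7 higher, 45 lower), and against both controls 3. Most of the 29 genes called in KD against 3NC were among the 52, in the same direction. That count therefore holds genes for which 3NC differed from KD as well.

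**Figure D1:**
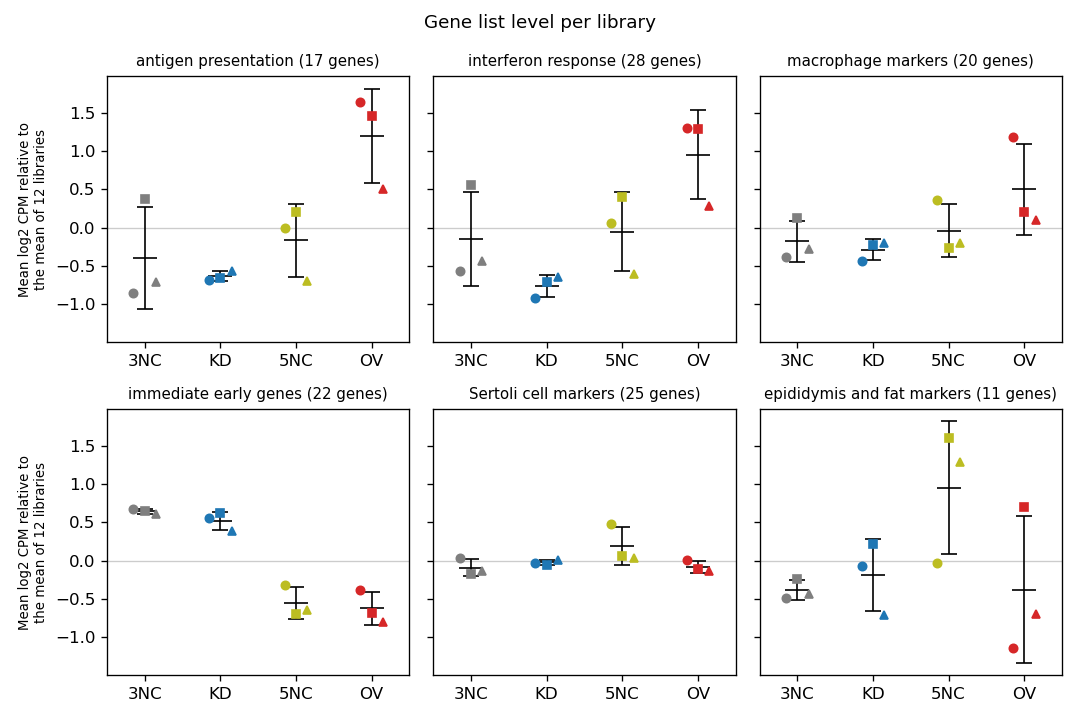
Mean log2 CPM of 6 gene lists in each library, relative to the mean of the 12 libraries; points are libraries (circle, square and triangle for replicates 1, 2 and 3) and bars are the mean ± SD (n = 3). Antigen presentation lies at 0.5 to 1.64 in OV, while immediate early genes lie at 0.39 or above in 3NC and KD and at −0.32 or below in 5NC and OV.

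KD against 3NC asks which testis genes respond to less of lncRNA8276. In KD 25 genes fell, among them Ccl2, Ccl7, Medag, Myc and Itga5, and 4 genes rose. Medag, a gene with a role in fat cell formation (gene 70717, chromosome 5, 149367641 to 149431723), fell from 12 ± 2.27 to 1.54 ± 0.174 CPM (SD, n = 3; edgeR adjusted p = 0.000129). Myc, the growth-promoting transcription factor (gene 17869, chromosome 15, 61985341 to 61990361), fell from 4.67 ± 0.409 to 0.663 ± 0.298 CPM (adjusted p = 0.00083). These genes stood as low in 5NC as in KD: 28 of the 29 genes were also called in 5NC against 3NC, in the same direction. Both comparisons use the 3NC libraries. Simulated unchanged groups shared at most 1 call in 5 draws, but such groups give few calls at all. The draws therefore cannot show how many of the 28 calls come from the shared 3NC libraries. Against 5NC the 25 genes had a median of 0.01 in KD, and 12 of them were lower by sign. Their median in OV against KD was 0.17 (SD 0.67 over genes), so most stood low in OV as well.

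Ccl2 and Ccl7, chemokine genes with few reads in KD, had the largest falls by fitted fold. Ccl2 had 150 reads in 3NC and 5 in KD (ratio 29.8, 95% counting interval 12.5 to 93.2; log2 fold change −4.79 ± 0.82), and Ccl7 148 and 7 reads (−4.31 ± 0.48). The chemokine gene Cx3cl1 had −1.76 ± 0.3. Medag had −2.96 ± 0.25 and Myc −2.8 ± 0.32. Itga5, the alpha chain of the fibronectin receptor (gene 16402, chromosome 15, 103344286 to 103366791), fell from 8.63 ± 0.653 to 1.98 ± 0.406 CPM (−2.12 ± 0.28). Socs3, a feedback inhibitor of cytokine signalling, had −2.6 ± 0.38, the nuclear receptor gene Nr4a3 −1.84 ± 0.25, Ier3 −1.82 ± 0.26 and Ugdh, which supplies glucuronic acid for matrix sugars, −1.66 ± 0.22. Osr1, a zinc finger transcription factor, rose from 0.468 ± 0.107 to 1.78 ± 0.532 CPM (1.91 ± 0.34). Txnip, an inhibitor of thioredoxin, rose by 0.83 ± 0.15 and Aldh3a1, an aldehyde dehydrogenase, by 1.81. Cyp3a41a had 0 reads in 3NC and 30 in KD, 10.1-fold higher against 3 reads over the group and at least 7.69-fold higher by the 95% counting interval of the ratio; it is uncertain because of its close paralogs. Kitl, the ligand of the KIT receptor made by Sertoli cells, fell from 33.3 to 17.4 CPM (−0.94 ± 0.15).

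**Figure D2:**
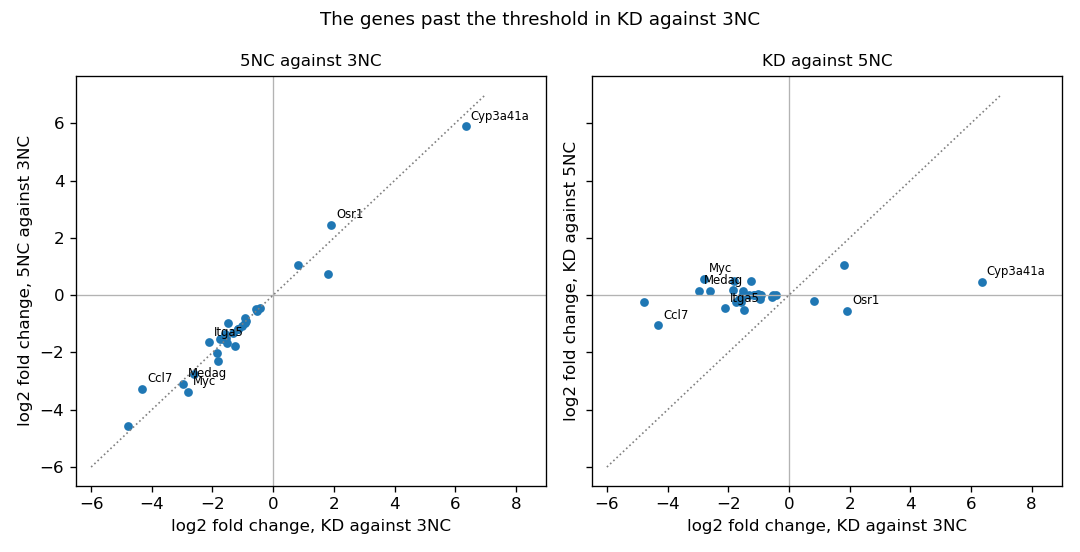
Log2 fold change of the 29 genes called in KD against 3NC (horizontal axes) plotted against that in 5NC against 3NC (left) and in KD against 5NC (right); each point is a gene and the dotted line marks equal values. Points follow the line on the left and scatter around 0 on the right, where the 25 lower genes have a median of 0.01; Cyp3a41a has 0 reads in 3NC, so its fitted values against 3NC are no bound.

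By camera, 8 lists passed in KD against 3NC, and 0 with an estimated correlation. Interferon response genes fell (27 of 28 lower, median −0.74, adjusted p = 3.24e-05; adjusted p = 0.65 with an estimated correlation; 0 adjusted over the list alone). Cxcl10 had −2.53, Rsad2 −1.87, Irf9 −0.87 and the RNA sensor gene Ifih1 −0.76. Inflammatory cytokines and chemokines fell (11 of 15 lower, median −0.26, adjusted p = 0.00148; adjusted p = 0.5 with an estimated correlation). Ccl2, Ccl7 and Cx3cl1 passed over all genes, 3 passed adjusted over the list alone, and Il1b had −0.47. Leydig cell and steroidogenesis genes fell (15 of 21 lower, median −0.16, adjusted p = 0.00122; adjusted p = 0.5 with an estimated correlation; 4 adjusted over the list alone). Among the members that passed adjusted over the list alone were Hmgcs1, an enzyme of sterol synthesis (−0.59), and Fdx1, an electron carrier of steroid synthesis (−0.61). NRF2 and oxidative stress genes fell (15 of 21 lower, median −0.05, adjusted p = 0.0086; adjusted p = 0.5 with an estimated correlation; 4 adjusted over the list alone). Hmox1, the haem-degrading enzyme, had −0.93 ± 0.21, Srxn1 −0.34, Mt2 −0.32 and Txnrd1 −0.29.

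Endothelial markers rose (16 of 18 higher, median 0.2, adjusted p = 0.000489; adjusted p = 0.5 with an estimated correlation; 1 adjusted over the list alone). Sox18 had 0.86, Cldn5 0.67, Eng 0.53 and Flt1, a VEGF receptor, 0.5. Erythrocyte genes did not pass (camera adjusted p = 0.216), with 5 of 5 higher and a median of 0.8. Ribosomal proteins rose (26 of 36 higher, median 0.08, adjusted p = 0.0086; adjusted p = 0.744 with an estimated correlation), with Rps15 at 0.3 and Rps20 at 0.18. Histones rose (7 of 7 higher, median 0.21, adjusted p = 0.0303; adjusted p = 0.5 with an estimated correlation). Elongating spermatid genes rose (19 of 23 higher, median 0.12, adjusted p = 0.0439; adjusted p = 0.818 with an estimated correlation), with Odf1, a sperm tail fibre protein, at 0.2 and the protamine Prm2 at 0.16. In each of these last 3 lists 0 members passed adjusted over the list alone, and reads of histone and ribosomal genes can be shared with paralogs and pseudogenes. Without 3NC replicate 2, 3 lists passed in place of 8: interferon response (adjusted p = 0.0958; median −0.13 in place of −0.74), inflammatory cytokines (0.089), ribosomal proteins (0.452), histones (0.415) and elongating spermatids (0.681) lost their calls. NRF2 was lost without 3NC replicate 3 (0.0641) or KD replicate 1 (0.162), histones without KD replicate 2 (0.0562) or 3 (0.0614), and elongating spermatids without KD replicate 3 (0.225). Against 5NC the endothelial (0.45), inflammatory (0.206), NRF2 (0.231) and histone (0.116) calls were lost, and ribosomal proteins fell (adjusted p = 0.000413; adjusted p = 0.667 with an estimated correlation). Histones (0.0872) and elongating spermatids (0.0524) were lost with a filter at 1 CPM, and elongating spermatids with a replicate block (0.0703).

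The other germ cell and junction lists did not pass in KD against 3NC. Undifferentiated spermatogonia had a median of −0.03 (camera adjusted p = 0.939), with Pou5f1 at 0.72, and differentiating spermatogonia 0.02 (0.87), with a test direction of down. Meiotic recombination genes had −0.06 (0.153), with Spo11 at −0.42, pachytene spermatocytes −0.02 (0.741), the piRNA pathway −0.05 (0.318), round spermatids 0.01 (0.631) and the flagellum −0.02 (0.694). Tight junctions had 0.07 (0.604), and adherens, desmosome and gap junctions −0.07 (0.509), with Cdh2 at −0.41, the 1 member lower adjusted over the list alone. Integrins had −0.01 (0.575), with Itga5 called, other adhesion molecules −0.06 (0.439), and Sertoli cell markers 0.08 (0.216), with Kitl called. Antigen presentation had −0.46 (0.216), macrophage markers −0.09 (0.631) and lymphocyte markers −0.06 (0.922), the last with a test direction of up. Immediate early genes had a median of 0.06, a mean of −0.13 and a test direction of down (0.772). Myc and Ier3 were called lower over all genes, and adjusted over the list alone 5 members were higher and 6 lower. The count of 29 genes was 70 with DESeq2 and 106 with voom and sample weights. Without single libraries it was 15 (3NC replicate 1), 12 (3NC replicate 2), 12 (KD replicate 1), 10 (KD replicate 2) and 10 (KD replicate 3), and without both 3NC replicate 2 and OV replicate 3 it was 18. Against 5NC edgeR called 8 genes, all higher and 0 of them among the 29, and against both controls 3.

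5NC against 3NC compares the control groups. Immediate early genes were lower in 5NC. Egr1, a transcription factor induced soon after a stimulus (gene 13653, chromosome 18, 34861207 to 34864956), had 4.5 ± 1.45 CPM in 5NC and 50.5 ± 3.66 in 3NC (SD, n = 3; −3.48 ± 0.18, edgeR adjusted p = 1.82e-07). KD had 52 ± 1.58 CPM and OV 4.32 ± 0.924. The immediate early list fell (19 of 22 lower, median −1.11, adjusted p = 1.32e-19; adjusted p = 0.0506 with an estimated correlation; fry adjusted p = 0.000367). Of its members 11 were called over all genes and 14 adjusted over the list alone, among them Myc at −3.37 ± 0.34, Egr2 at −3.1 and Btg2 at −2.37. Ccl2 (−4.56 ± 0.8), Ccl7 (−3.26 ± 0.43) and Medag (−3.1 ± 0.25) fell as well. Among the rises were Spink8 (3.79 ± 0.63), Osr1 (2.45 ± 0.33), Fbxo32, a ubiquitin ligase subunit (1.67 ± 0.32), and Ramp1 (1.58 ± 0.27). In all, 59 genes changed, 12 higher and 47 lower. The count was 151 with DESeq2, 134 with voom and sample weights and 31 with limma on FPKM. It was 39, 32 and 32 without 3NC replicates 1, 2 and 3, 34 without 5NC replicate 2 and 16 without 5NC replicate 3.

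Sertoli cell markers rose in 5NC (24 of 25 higher, median 0.27, adjusted p = 9.11e-05; adjusted p = 0.613 with an estimated correlation), with 2 higher and Kitl (−0.8) lower adjusted over the list alone. Ribosomal proteins rose (35 of 36 higher, median 0.15, adjusted p = 1.25e-07; adjusted p = 0.613 with an estimated correlation), with 1 adjusted over the list alone. Epididymis and fat markers rose (8 of 11 higher, median 0.84, adjusted p = 0.0374; adjusted p = 0.613 with an estimated correlation), with Spink8 and Plin1 (1.47) called and 4 adjusted over the list alone. Adam7 had 2 reads in 3NC and 365 in 5NC (ratio 186, 95% counting interval 51.2 to 1540), and the 5NC libraries differed, with 9, 79 and 277 reads in replicates 1, 2 and 3. Tight junctions (15 of 19 higher, median 0.2) and endothelial markers (14 of 18 higher, median 0.17) rose at an adjusted p of 0.0359 each (adjusted p = 0.613 with an estimated correlation), each with 1 adjusted over the list alone. Pachytene spermatocyte genes fell (15 of 20 lower, median −0.08, adjusted p = 0.0374; adjusted p = 0.627 with an estimated correlation; 0 adjusted over the list alone). Of the lists that did not pass, elongating spermatids (median 0.04) and adherens, desmosome and gap junctions (0.01) had a test direction of down, and integrins (median 0.09, mean −0.01) one of up. Without 5NC replicate 1 the Sertoli (adjusted p = 0.125), tight junction (0.155), endothelial (0.133) and pachytene (0.383) calls were lost. Without 3NC replicate 3 the tight junction (0.165), endothelial, epididymis and fat, and pachytene (0.0837 each) calls were lost. The epididymis and fat call was also lost without 5NC replicate 2 (0.342), and the pachytene call without 3NC replicate 2 (0.0914). In place of 7 lists, 12 passed without 3NC replicate 2, 3 without 3NC replicate 3, 3 without 5NC replicate 1, 11 without 5NC replicate 2 and 3 with library size as the only scaling. Scaling by library size alone ended the tight junction and endothelial (0.0535 each) and the epididymis and fat and pachytene (0.0738 each) calls.

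**Figure D3:**
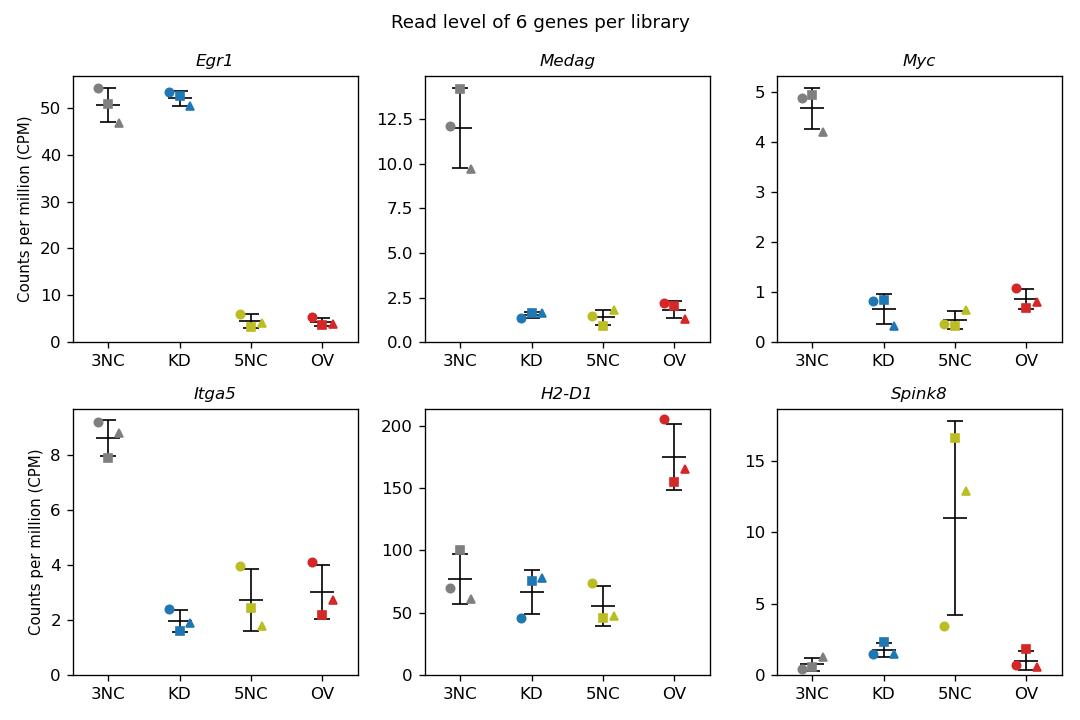
CPM of 6 genes in each library of the 4 groups; points are libraries (circle, square and triangle for replicates 1, 2 and 3) and bars are the mean ± SD (n = 3). Egr1 averages 50.5 in 3NC and 52 in KD against 4.5 in 5NC and 4.32 in OV, and Myc averages 4.67 in 3NC and under 1 in the other groups.

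The OV and KD effects were compared directly, to ask whether more and less of lncRNA8276 move genes in opposite directions. The difference passed for 10 genes, 9 of them with a higher OV effect, led by Medag (3.35 ± 0.37, edgeR adjusted p = 0.00452), Ifrd1, Ccl7 and Myc. For these 4 genes and Errfi1, Trib1 and Sema4b the KD effect carried most of the difference: OV against 5NC gave 0.39 for Medag, 0.28 for Ifrd1, 1.15 for Ccl7, 0.94 for Myc, 0.09 for Errfi1, −0.05 for Trib1 and −0.1 for Sema4b. None of these OV values passed, and the 7 genes had their highest group mean in 3NC. By camera 10 lists differed, and 0 with an estimated correlation (smallest adjusted p = 0.435) or with fry (smallest 0.126). The largest medians were in antigen presentation (1.86, adjusted p = 1.66e-08; adjusted p = 0.435 with an estimated correlation) and interferon response (1.77, adjusted p = 2.85e-11; adjusted p = 0.435 with an estimated correlation). Adjusted over the list alone, 14 of 17 and 17 of 28 of their members passed. The KD part of the interferon value depended on 3NC replicate 2: without it the KD median was −0.13 in place of −0.74. DESeq2 called 87 genes and voom with sample weights 53. Without single libraries the count was 5 (3NC replicate 1), 5 (5NC replicate 3), 6 (KD replicate 1), 5 (KD replicate 2), 4 (KD replicate 3), 23 (OV replicate 2) and 19 (OV replicate 3).

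No gene was called in both comparisons, since OV against 5NC had 0 calls with edgeR (1697 at an unadjusted p under 0.05; 45 with DESeq2, 7 with voom and sample weights). Of the 215 genes called with a block in OV and 5NC alone, Cyp3a41a (1.65 ± 0.43) was also called in KD against 3NC, higher in both. The 200 genes of smallest p in each shared 9, against 2.45 for independent lists (two-sided Fisher exact p = 0.000819). Of 60 splits of the same libraries, the real one included, 30 shared at least 9, so this overlap did not exceed that of other splits. Lhfpl3, Stxbp3, Cox7b, Atxn7, LOC100044068 and Ifi204 had higher values in OV and lower in KD, Kcnk3 the reverse, and Cyp3a41a and Arhgap40 higher values in both. Without single libraries the shared number was 6 (3NC replicate 2), 6 (5NC replicate 2) and 6 (KD replicate 1). Across all genes, which are not independent replicates, the log2 fold changes had r = −0.26 and rho = −0.37. Without 3NC replicate 2 r was −0.09, without KD replicate 2 −0.13, and with the controls exchanged −0.24.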

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

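The tests in the 3 patterns weighed first were chosen after the results were seen; the counts of other splits of the samples were planned, except that the difference of effects was counted over splits that part the pairs afterwards, and that the replicate block for OV and 5NC alone was chosen after the data were seen.

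The 25 genes lower in KD than in 3NC, Myc, Medag and Ccl2 among them, were as low in 5NC, which targets nothing by the inferred design. A knockdown that alone lowers them from a level both controls share is argued against by the median of KD against 5NC, 0.01 (SD 0.33 over genes), far from the −1.52 against 3NC. Without 3NC replicate 2 the median was −1.44 (SD 1.05), so for these genes the difference did not rest on that library alone. Calling favours genes whose 3 libraries agree, so such a value was likely for any called genes and is weak evidence. A level that the 3NC libraries alone have stays open, with OV against KD at 0.17 (SD 0.67). All 25 genes were called lower in 5NC than in 3NC. In OV they were called lower than in 3NC too, except Bach1, Kitl, Mat2a, Ccl2 and Frmd6. What would set 3NC apart, and whether a knockdown effect adds to a vector difference, was not tested. KD against 3NC and 5NC against 3NC share the 3NC libraries. In 5 simulated draws of unchanged groups at most 1 call was shared, against 28 here, but unchanged groups give few calls at all. The draws therefore cannot show how much of this number comes from the shared libraries. In these draws the log2 fold changes of both comparisons had a mean correlation of 0.48, against 0.55 observed.

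Antigen presentation and interferon response genes were higher in OV than in 5NC. A sequence variant of the MHC region on chromosome 17 as the whole cause is argued against by the 5 antigen presentation genes outside it, all 5 higher with a median of 1.38 (SD 0.57). More immune cells in OV may contribute: macrophage markers, which share no gene with the other lists, had a median of 0.68 (SD 0.46), with C1qb at 22.2 CPM in OV and 13.6 in 5NC and Ctss at 22 and 8.56. Without OV replicate 1 their median was 0.19 and that of antigen presentation 1.19, so a contribution of such cells stays open. Marker levels in RNA of whole tissue cannot tell more cells from more RNA per cell. A response that follows the dose of lncRNA8276 also stays open, since the interferon list in KD had a median of −0.13 (SD 0.53) without 3NC replicate 2. Against 5NC the list was lower in KD by camera with the preset correlation (adjusted p = 1.56e-08). Its means per library were −0.92, −0.71 and −0.65 in KD and 0.06, 0.4 and −0.61 in 5NC.

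Immediate early genes, such as Egr1 and Btg2, were higher in 3NC and KD than in 5NC and OV. The level of lncRNA8276 alone is argued against by the control groups, which differ by a median of −1.11 (SD 1.19) with 11 of 22 genes called. A difference in handling or timing between the vector series could account for it; OV against KD had −0.67 (SD 1.21), but series and vector coincide in this design and cannot be told apart.

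The following 10 genes differed between the OV and KD effects by the test of the difference itself, given as log2 differences. Medag had 3.35, Ifrd1, a transcriptional coregulator, 1.29, the chemokine Ccl7 5.46 and Myc 3.75. Kcnk3, a potassium channel, had −2.74, with 1.33 CPM in OV, 4.17 in 5NC, 3.89 in KD and 1.82 in 3NC. Errfi1, an inhibitor of EGF receptor signalling, had 1.35, Lhfpl3 3.3, the pseudokinase gene Trib1 1.47 and the semaphorin gene Sema4b 1.39. Lhfpl3 had 1.74 CPM in OV, 0.357 in 5NC, 0.92 in KD and 1.91 in 3NC, so its mean too was highest in 3NC. Medag, Ifrd1, Ccl7, Myc, Errfi1, Trib1 and Sema4b had their highest mean in 3NC: Medag had 12 CPM there and 1.39 in 5NC, 1.54 in KD and 1.83 in OV, and Myc 4.67 against 0.445, 0.663 and 0.864. These 7 genes were called lower in KD, in 5NC and in OV than in 3NC, and none was called in KD or OV against 5NC. By these calls 3NC alone stood apart for them. What would set 3NC apart, and whether a knockdown effect adds to it, was not tested. Cox7b, a subunit of cytochrome c oxidase, had 1.48, with 15.1 CPM in OV, 9.88 in 5NC, 8.12 in KD and 14.8 in 3NC. Without single libraries this count of 10 was 5 (3NC replicate 1), 5 (5NC replicate 3), 6 (KD replicate 1), 5 (KD replicate 2), 4 (KD replicate 3), 23 (OV replicate 2) and 19 (OV replicate 3).

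Other splits of the same samples were counted for each model. For the difference of effects, 2 of 60 splits drawn, the real one included, gave at least 10 genes, and the highest other gave 20. These splits did not keep the pairs of OV with 5NC; among the 80 that part all 3 pairs, as the real one does, 1, the real one, gave 10 genes or more, and the highest other gave 7. By both counts the share lay under 0.05. For 7 of the genes, though, the KD effect carried most of the difference. KD with 3NC alone has 10 splits, too few for a share under 5%. The joint splits therefore do not exclude chance for this count, which itself depends on single libraries. For the overlap of 9 genes, 30 of 60 splits gave as many (highest other 16), so chance cannot be excluded for it. For the size of the correlation, 0.26, 4 of 60 did (highest other 0.27). These splits include exchanges of KD with 3NC, which reverse the sign of r and keep its size. That count therefore does not weigh the direction. With its sign, r reached −0.27 in another split, so chance cannot be excluded here either. With 3 libraries against 3 there are 10 splits, too few for a share under 5%. Among them, as many genes came from 10 splits for OV against 5NC (real value 0, highest other 1), 1 split for KD against 3NC (29, highest other 0) and 1 for 5NC against 3NC (59, highest other 1). For gene lists the numbers were 7 for OV (8, highest other 21), 2 for KD (8, highest other 9) and 6 for 5NC (7, highest other 11). The split with 21 lists sets 5NC replicates 1 and 3 and OV replicate 1 against the rest. It may reflect a structure of the samples besides the groups or the preset correlation of the list test, which were not told apart by a test. With a replicate block for OV against 5NC, 4 splits part all 3 pairs, again too few; 1 gave as many as the real 215 genes, and the highest other gave 11.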

How the results depend on the processing

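The fits without both 3NC replicate 2 and OV replicate 3, the blocks for OV and 5NC, and the list tests with other scaling or the other control were chosen after the data were seen; the rest were planned. Scaling by RLE factors, no filter, the 1 CPM filter, a fold threshold and the planned block left the counts of called genes within 1.5 times the reported value. The block left 22 genes for KD, 50 for 5NC and 13 for the difference. DESeq2 called 45 genes for OV, 70 for KD, 151 for 5NC and 87 for the difference, and voom with sample weights 7, 106, 134 and 53. limma on FPKM called 31 for 5NC. An unadjusted p under 0.05 gave 1697, 979, 1972 and 2560 genes. Against the other control OV had 52 genes and KD 8, and the overlap was 17; against both controls pooled each had 3. With an estimated correlation 0 lists passed for OV, 0 for KD and 0 for 5NC, and with fry 0, 0 and 1; library size as the only scaling left 3 lists for 5NC. Without both libraries there were 36 genes for OV, 18 for KD, 3 lists for KD and 12 lists for 5NC. A block in a fit of OV and 5NC alone gave 215 genes, and one within the fit of all groups 2. With single libraries left out the counts ran from 0 to 5 for OV, 10 to 22 for KD, 16 to 66 for 5NC and 4 to 23 for the difference; lists ran from 10 to 14 for OV, 3 to 11 for KD and 3 to 12 for 5NC; the overlap ran from 6 to 12 and r from −0.26 to −0.09. The cause was not tested for any of these. Fewer libraries give fewer degrees of freedom, but some counts rose when a library was left out.

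Directions reversed against the other control. For OV these were Lhfpl3 −0.13, Ramp1 0.08, Spink8 0.39, Plin1 0.72, Adam7 2.94, Crisp1 0.4, Nr5a1 0.09, Amhr2 0.01, Defb45 0.27, Cldn5 0.47, Ocln 0.01, Nlgn2 0.02, Nme8 −0.02, Tex29 −0.05, Catsper3 −0.01 and Cabs1 −0.01. For KD they were Osr1 −0.54, Txnip −0.21, Medag 0.14, Myc 0.57, Socs3 0.16, Nr4a3 0.17, Ier3 0.49, Cldn5 −0.14, Il1b 0.33, Hmgcs1 0.18, Hmox1 0.07, Srxn1 0.06, Hist1h1c −0.28, Rps15 −0.06, Rps20 −0.01, Rps27 −0.03, Pou5f1 −0.13, Kit −0.08, Sycp2 0.04 and Mybl1 0.05. Against pooled controls Cldn5 in OV had 0.07, and Hist1h4a in KD ran from −0.02 (without 3NC replicate 2, with or without OV replicate 3) to 0.35. The cause was not tested. Alternatives for a table of normalised values alone (another pseudocount, FPKM filters, quantile scaling) and for the targeted RNA did not apply and were not run. Depth limits genes near 3 reads, 0.183 to 0.194 CPM.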

Other observations

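KD against 5NC was planned as an exchanged control; the pooled comparison of 3NC and KD with 5NC and OV, the vector series by their inferred assignment, and the closeness of libraries were chosen after the results were seen.

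Immediate early genes did not share a single pattern across the groups. Egr1, Btg2, Fos, Fosb, Zfp36, Ier2 and Junb, stimulus-induced regulators, were called higher in KD than in 5NC, and 21 of 22 list members were higher there, with a median of 0.64 (adjusted p = 0.011 with an estimated correlation). Myc, Ier3 and, outside the list, Nr4a3 were instead called lower in KD than in 3NC, and against 5NC they had 0.57, 0.49 and 0.17 in KD, none of them called. Pooled, 3NC and KD exceeded 5NC and OV in all 22 members, with a median of 1.22, and 12 members passed (camera adjusted p = 1.85e-45; adjusted p = 0.00308 with an estimated correlation). The list means per library were 0.68, 0.65 and 0.61 in 3NC and 0.56, 0.62 and 0.39 in KD, against −0.32, −0.7 and −0.64 in 5NC and −0.38, −0.68 and −0.8 in OV.

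Across genes, 3NC replicate 2 and OV replicate 3 were closer to each other than either was to the other libraries. The chi-square per gene between them was 5.84, against 19.88 to 29.67 for 3NC replicate 2 and 16.79 to 27.37 for OV replicate 3 with the others. The correlation of their log2 CPM, taken as deviations from the mean of all libraries, was 0.28. Erythrocyte genes differed within OV, with list means of 0.63, −0.45 and −1.32 for replicates 1, 2 and 3.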
